A study of Mus musculus with 16 samples.

How the data were processed

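RNA sequencing counts were analysed from mouse neural stem and progenitor cells grown as neurospheres from the cortices and ganglionic eminences of foetuses at embryonic day 14.5. Null cells came from foetuses homozygous for a floxed Kat7 allele and intact cells from foetuses with wild-type Kat7. Both carried a Cre transgene driven by Nestin sequences, so that Cre itself was present in both genotypes. Cells were isolated from 4 foetuses per genotype and sampled while proliferating, after 3 passages and 3 days, or after 3 days of differentiation on laminin in a medium for cortical neurons, plated at 20000 cells per square centimetre. This gave 4 groups of 4 libraries (null proliferating, intact proliferating, null differentiating, intact differentiating). Polyadenylated RNA had been sequenced as 75-base paired-end reads. With 4 foetuses per genotype, the same foetuses may have given proliferating and differentiating libraries. Which libraries would match is not given in the sources used here. Residual correlations of the proliferating and differentiating libraries with the same number were 0.126, 0.123, -0.231 and 0.117 in intact cells and -0.0284 to 0.0331 in null cells. No intact proliferating library correlated best with the differentiating library of its own number, and 1 null proliferating library did. Pairing stays open, so the fit had no block and blocks were run as alternatives. The isolate blocks took libraries of a genotype with the same number as 1 foetus, which is an assumption.

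The deposited values are raw read counts per gene, 1 library per file, beside the length of each gene model in bases per the file headers. According to the submitters' processing notes, reads were demultiplexed with bcl2fastq and counted with featureCounts against mm10. Versions, aligner, annotation and strandedness are not given in the sources used here, so reads of overlapping or antisense genes, and of close paralogs such as Fnd3c2 and Fndc3c1, cannot be told apart. The files were checked to hold whole numbers with a different total in each library. Of 27179 genes, 25275 identifiers were matched to symbols and positions with the RefSeq table of GRCm38, the assembly that mm10 names. Among them were Sox10 (Entrez 20665; chromosome 15, 79154913 to 79164490), Slc1a2 (20511; chromosome 2, 102658239 to 102790784), Egfr (13649; chromosome 11, 16752203 to 16913907), Neurod6 (11922; chromosome 6, 55677818 to 55681263) and Gsx1 (14842; chromosome 5, 147188696 to 147190947). A combined table with the same counts was not used.

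Library totals were 16.8 to 47.9 M counts, with 16322 to 18774 genes detected and 4.15 to 6.53% of the counts in the 10 most abundant genes. Replicates correlated at a Pearson r of 0.948 to 0.994 on log2 CPM, and no library was a copy of another. Xist had 28175 to 189634 counts and 4 Y-linked genes together 0 to 5 counts in every library, so all libraries read as female and sex could not be a covariate.

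Counts were fitted in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups with a minimum count of 10, which left 15177, and scaled by trimmed mean of M values (TMM). A quasi-likelihood model with 1 mean per group and no covariate was fitted to all 16 libraries (common biological coefficient of variation 0.200). Contrasts were null against intact in proliferating and in differentiating cells, differentiating against proliferating in intact and in null cells, and the difference of these responses (interaction, the null response minus the intact response). Benjamini-Hochberg adjusted p under 0.05 was called. Fold changes are log2. The standard error (SE) beside each was taken as the unshrunk estimate over the square root of the test's F statistic. It can be too small where a group has few counts. Log2 CPM used a prior count of 2 for principal components, list means and set tests. For a gene without counts in a group, the fold was computed against a floor of 3 counts over the group and is a lower bound, and with 1 to 3 counts the ratio is given with its 95% counting interval. No spike-in was used, so all changes are relative to the other genes of a library.

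The comparisons, tests, gene lists, processing alternatives and the rule for named genes were chosen before the data were examined. That rule took Kat7, then the 10 highest and 10 lowest fold changes of each genotype contrast and the 6 highest and 6 lowest of the others, among called genes with a mean of at least 2 CPM in the higher group and no overlap between libraries (the last not for the interaction), leaving out predicted genes, pseudogenes, Xist and Y-linked genes. From each list called by camera or with 3 called members it took up to 4 called members with the lowest adjusted p, and any other member could be named. Which of these are printed, and for which group levels are given, was decided after the values were seen. Some genes that met the rule are not reported here, and the checks of named genes leave them out. The 29 lists (621 symbols, 606 found, 485 tested) were KAT7 complex subunits, other lysine acetyltransferases, neural stem cell genes, mitotic cell cycle, DNA replication licensing, pan-neuronal, GABAergic and ventral forebrain, glutamatergic and dorsal forebrain, astrocyte, oligodendrocyte lineage, synapse and ion channel, Notch pathway, WNT and BMP target, p53 target, CDK inhibitor and senescence, HOX, non-neural lineage regulators, microglia and leukocyte, endothelial, pericyte and fibroblast, ependymal and choroid plexus, erythroid, neural crest and Schwann cell, interferon response, unfolded protein and integrated stress response, hypoxia and glycolysis, cholesterol synthesis, immediate early, and mitochondrially encoded genes. They serve as gene groups, and no cell types are called from them. HOX and erythroid genes had 1 tested member each and no set test.

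Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within a contrast, with an estimated correlation, and with fry. No camera call held with an estimated correlation in any of the 5 contrasts. Genes activated on differentiation were chosen on the mean response of both genotypes (adjusted p under 0.05, mean log2 fold change over 1) and divided at 0.5 CPM in proliferating cells, and the mean log2 CPM per library was compared by exact two-sided permutation tests. Overlaps of called genes are given beside the number for independent lists of the same sizes. All other divisions of the compared libraries into groups of 4 were fitted in the same way, 35 per contrast with the real one, or 60 drawn for the interaction and the overlap.

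The fit was tested on simulated data with planted changes in 100 genes per fold. It recovered 66, 59, 70, 72 and 53% of 2-fold changes and 87, 94, 88, 94 and 79% of 4-fold changes in the 5 contrasts in the order above, with 7.27, 3.16, 4.82, 2.35 and 8.97% of calls false. The simulated genes were independent and far fewer were changed than were called in the data, so these rates need not carry over. Alternatives were DESeq2 size factors (RLE) in the same fit, library size alone, DESeq2 1.42.0 with its Wald test, limma voom with quality weights, no count filter, at least 1 CPM in 4 libraries, a test against 1.5-fold (glmTreat), only the libraries compared, replicate number as a block, isolate as a fixed or random block, each library left out in turn, and for the activated genes other limits, prior counts and a choice on part of the intact libraries. A fit without intact proliferating replicate 1 and intact differentiating replicate 1, the pair of libraries that stood apart on the principal components, was added after seeing the data.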

Results

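Kat7, which encodes the histone lysine acetyltransferase KAT7 (HBO1), was expressed at 139 ± 5.59 CPM (counts per M counts of the library, mean ± SD, n = 4) in intact proliferating cells and at 103 ± 3.08 CPM in intact differentiating cells. In the null cells the gene (Entrez 217127; chromosome 11, 95271853 to 95310246 in GRCm38) had 8 counts over the 4 proliferating libraries and 1 count over the 4 differentiating libraries. These were 0.0551% (95% counting interval 0.0238 to 0.109%) and 0.00680% (0.000172 to 0.0379%) of the intact level. Every null library was below every intact library, and edgeR's quasi-likelihood test gave log2 fold changes of -10.73 ± 0.25 (SE, adjusted p = 4.7e-13) and -13.13 ± 0.31 (adjusted p = 3.3e-13). With so few null counts these SE are narrower than the counting intervals and understate the error. In intact cells, Kat7 fell by 0.44 ± 0.13 on the log2 scale upon differentiation (edgeR adjusted p = 0.00647), a change that did not pass a test against a minimum of 1.5-fold. Intervals here and bounds on genes without counts cover counting error only.

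The 4 groups of libraries separated on the first 2 principal components, which held 58.9% and 24.1% of the variance of log2 CPM. On component 1, null proliferating libraries scored -109 to -99.0, intact proliferating replicates 2 to 4 scored -72.0 to -65.8, null differentiating libraries 36.1 to 42.3 and intact differentiating libraries 102 to 136. Intact proliferating replicate 1 lay apart from its group at -7.60. Intact differentiating replicate 1 was at the other end, at 136.

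**Figure D1:**
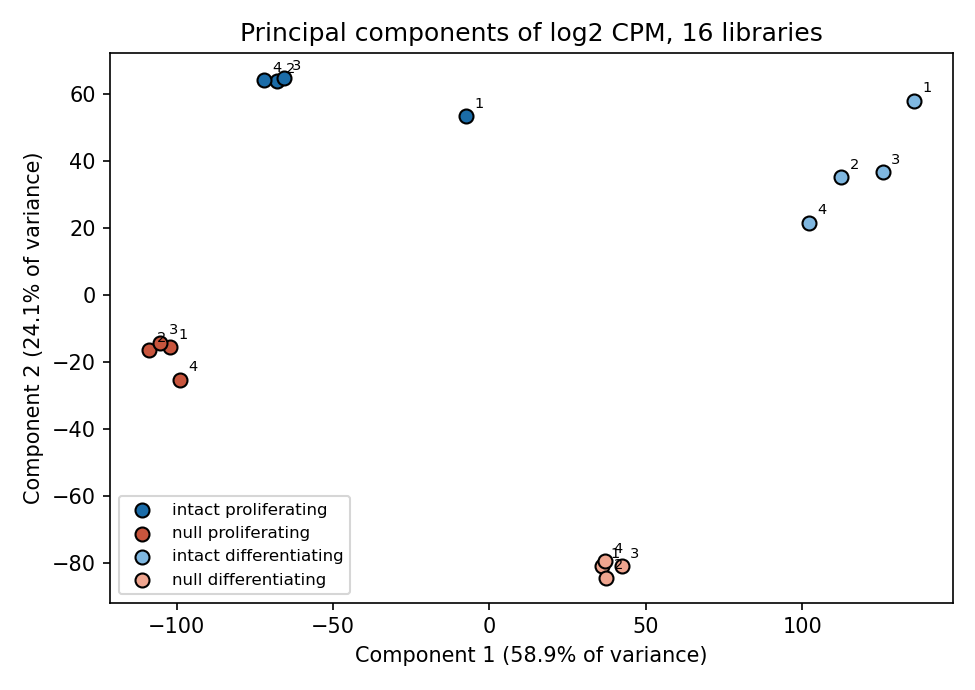
Scores of the 16 libraries on principal components 1 (x axis, 58.9% of the variance) and 2 (y axis, 24.1%) of log2 CPM, with 1 point per library, colour for the group and the replicate number beside each point. Null libraries lie to the left of intact libraries of the same culture condition, and intact proliferating replicate 1 lies at -7.60 on component 1, to the right of the other proliferating libraries.

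In proliferating cells without KAT7, genes of the oligodendrocyte lineage were far below their level in intact cells. Sox10, a transcription factor of this lineage, was at 2.43 ± 0.241 CPM in null and 46.9 ± 40.4 CPM in intact proliferating cells (log2 fold change -4.26 ± 0.55, edgeR adjusted p = 3.0e-05). Ugt8a, an enzyme of myelin lipid synthesis, was at 0.303 ± 0.0651 CPM against 23.8 ± 16.3 CPM (-6.22 ± 0.53, edgeR adjusted p = 8.7e-07). Lhfpl3 fell by 3.11 and the progenitor proteoglycan gene Cspg4 by 2.16 on the log2 scale. Of 24 oligodendrocyte lineage genes, 16 fell and 2 rose, with 17 and 2 adjusted over the list alone (median log2 fold change -2.11, camera adjusted p = 6.8e-04, adjusted p = 0.954 with an estimated correlation). Intact proliferating replicate 1 had a mean log2 CPM of 5.60 over this list, against 3.50 to 4.16 in the other intact proliferating libraries and 2.25 to 2.83 in the null libraries. Without this library and intact differentiating replicate 1, a pair chosen after seeing the data, 17 members fell and 4 rose.

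Genes for synapses, ion channels and glutamatergic neurons were also lower in the null proliferating cells. Of 35 synapse and ion channel genes, 15 fell and 2 rose, with 18 and 3 adjusted over the list alone (median -0.84, also with genes without counts at their bound; camera adjusted p = 0.0054). Rims1, a protein of the presynaptic active zone, fell by 4.26 ± 0.50 (edgeR adjusted p = 1.3e-05) and the GABA receptor subunit gene Gabra2 by 5.72 ± 0.76 (edgeR adjusted p = 3.8e-05). Of 19 glutamatergic and dorsal forebrain genes, 9 fell, among them Sox5 (-1.78 ± 0.10) and Foxp2 (-3.22 ± 0.75), and 1 rose. Adjusted over the list alone, 11 fell and 1 rose (median -3.18, or -2.30 with 4 genes without counts at their bound; camera adjusted p = 0.015). Both lists had an adjusted p = 0.954 with an estimated correlation. Pan-neuronal genes did not pass the set test (camera adjusted p = 0.133), with 10 of 30 lower and 1 higher over all genes and over the list alone. Syt1, the calcium sensor of synaptic vesicles, was at 1.17 ± 0.375 CPM against 19.8 ± 8.59 CPM (-4.09 ± 0.59, edgeR adjusted p = 7.8e-05). The glutamatergic call was lost without intact proliferating replicate 1 (median -1.85, camera adjusted p = 0.0967) and under library size scaling (0.0504). The mean log2 CPM of that library over the list was 1.84 against 0.23 to 0.40 in the other 3 intact libraries.

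Astrocyte genes moved the other way. Slc1a2, the main glial glutamate transporter, rose from 47.8 ± 11.3 to 246 ± 41.8 CPM (2.36 ± 0.23, edgeR adjusted p = 3.2e-06) and Sparcl1, a matricellular protein of astrocytes, from 190 ± 58.1 to 858 ± 267 CPM (2.18 ± 0.23, edgeR adjusted p = 5.2e-06). Of 25 astrocyte genes, 10 rose and 2 fell, over all genes and adjusted over the list alone (median 0.49, camera adjusted p = 0.0055, adjusted p = 0.954 with an estimated correlation). Fgfr3 was among the lower members (-0.88 ± 0.11). Null proliferating replicate 4 had a mean log2 CPM of 5.85 over this list against 5.02 to 5.10 in the other null libraries, and intact proliferating replicate 1 had 5.49 against 3.97 to 4.28. Without intact proliferating replicate 1 and intact differentiating replicate 1, 17 members rose and 2 fell.

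Mitotic genes were slightly lower and genes of the unfolded protein and integrated stress responses higher. Of 24 mitotic genes, 11 fell and none rose, with 12 and 0 adjusted over the list alone (median -0.30, camera adjusted p = 0.0013). Ccnb2, a mitotic cyclin, fell by 1.54 ± 0.17 (edgeR adjusted p = 8.9e-06) and the kinase gene Aurkb by 0.71 ± 0.13, the latter not passing the test against 1.5-fold. Of 20 stress response genes, 10 rose and 2 fell, with 12 and 2 adjusted over the list alone (median 0.53, camera adjusted p = 0.0043). Slc7a11, the cystine transporter, rose from 18.9 ± 1.43 to 203 ± 65.6 CPM (3.42 ± 0.24, edgeR adjusted p = 1.4e-07). The chaperone gene Dnajb9 (0.73 ± 0.13) and Shmt2 (0.71 ± 0.13), an enzyme of mitochondrial one-carbon metabolism, changed less and did not pass the test against 1.5-fold. Each of these lists had an adjusted p = 0.954 with an estimated correlation. No call was made for 24 DNA replication licensing genes (0 higher, 2 lower, camera adjusted p = 0.429) or 25 neural stem cell genes (5 higher, 4 lower, camera adjusted p = 0.934). Nor was 1 made for 28 p53 target genes (3 higher, 3 lower, with 3 and 2 adjusted over the list alone, camera adjusted p = 0.934). In intact proliferating replicate 1, 12 p53 targets that changed at least 4-fold upon differentiation lay a median of 62.9% of the way to the differentiating level. The p53 list was not retested without that library in this contrast.

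Among all genes, 2879 were higher and 2985 lower in null than in intact proliferating cells (784 and 1263 by more than 2-fold). With library size scaling alone, 2234 were higher and 3847 lower. The lower share of the called genes was then 63.3% rather than 50.9%. The genes with the largest falls and no counts in any null proliferating library were Marchf1 (at least 182-fold lower), Dpp10 (at least 165-fold), Gabra3 (at least 102-fold), Bmp4 (at least 97.4-fold), Nrxn3 (at least 94.1-fold), Cbln2 (at least 84.9-fold) and Vstm2b (at least 83.2-fold). Plppr5, Adamtsl3 and Vgll2 were at 0.129% (0.00327 to 0.722%), 0.187% (0.0385 to 0.548%) and 0.277% (0.00698 to 1.55%) of the intact level. Higher were Klf14 (intact cells at 0.643%, 0.0776 to 2.34%, of the null level), Fam43b (6.72 ± 0.88), Kcne4 (5.43 ± 0.84) and Fgl2 (5.16 ± 0.49; 84.0 ± 36.6 against 2.34 ± 0.395 CPM). Crispld2, Pitx3, Ctxn3, Slc22a4, Lpin3 and the smooth muscle actin gene Acta2 (4.25 ± 0.48) followed, and edgeR adjusted p for these 10 genes lay between 7.8e-08 and 1.3e-04. By the rule that chose these 20 genes, no library of 1 genotype overlapped the other. Of the 35 splits of the 8 proliferating libraries into groups of 4, 23 called at least as many lists as the 6 called here. The number of lists called is therefore no support by itself. Members of a list are not independent either, and 38.6% of all tested genes were called in this contrast.

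In differentiating cells without KAT7, many neuronal genes were far below the level of intact cells. Syt1 was at 1.62 ± 0.573 CPM in null and 94.1 ± 76.6 CPM in intact differentiating cells (-5.86 ± 0.59, edgeR adjusted p = 2.3e-06), and the neurofilament gene Nefl fell by 3.80 ± 0.49 (edgeR adjusted p = 2.2e-05). Of 30 pan-neuronal genes, 20 were lower and 2 higher, with 22 and 2 adjusted over the list alone (median -1.48, camera adjusted p = 1.6e-05). Their changes were uneven. Dcx, a microtubule protein of young neurons, was at 343 ± 19.7 against 848 ± 636 CPM (-1.31 ± 0.58, edgeR adjusted p = 0.0761). Tubb3, a neuronal tubulin, was at 306 ± 42.3 against 512 ± 434 CPM (-0.74 ± 0.48, edgeR adjusted p = 0.225). Intact differentiating replicate 1 had 1138 CPM of Tubb3, 1780 CPM of Dcx and 204 CPM of Syt1, and the other 3 intact libraries averaged 304, 538 and 57.6 CPM. Of 35 synapse and ion channel genes, 22 fell and 3 rose, with 24 and 3 adjusted over the list alone (median -1.54, camera adjusted p = 2.1e-05). They included the sodium channel gene Scn1a (-5.37 ± 0.61) and the AMPA receptor subunit gene Gria4 (-6.76 ± 0.80). With an estimated correlation, both lists had an adjusted p = 0.537. Mean log2 CPM over the pan-neuronal genes was 4.63 to 4.80 in the null libraries and 5.70 to 8.07 in the intact libraries, highest in intact differentiating replicate 1. Without that library and intact proliferating replicate 1, 21 members were lower and 4 higher.

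Glutamatergic genes were lower, and GABAergic genes had no common direction. Neurod6, a transcription factor of cortical projection neurons, was at 0.270 ± 0.300 CPM in null and 99.0 ± 102 CPM in intact differentiating cells (-8.34 ± 0.98, edgeR adjusted p = 1.0e-05). Intact differentiating replicate 1 had 249 CPM and the other 3 intact libraries averaged 48.9 CPM. Eomes (-5.26 ± 0.63) and Tbr1 (-6.86 ± 0.94), further regulators of this lineage, fell too. Of 19 glutamatergic and dorsal forebrain genes, 12 were lower and 1 higher, over all genes and adjusted over the list alone (median -3.97, camera adjusted p = 5.5e-04, adjusted p = 0.537 with an estimated correlation). The 21 GABAergic and ventral forebrain genes went both ways, with 6 higher and 7 lower in both adjustments, a median of 0.45, a mean of -0.74 and no call (camera direction up, adjusted p = 0.891). Among the higher members, Gsx1 was at 40.6 ± 9.83 against 2.67 ± 2.10 CPM (3.93 ± 0.49, edgeR adjusted p = 1.5e-05), and Dlx2 (2.27 ± 0.48, edgeR adjusted p = 0.00129) and Sp9 (2.74 ± 0.45) rose. Lhx6, a regulator of interneurons, was at 0.198% (0.00500 to 1.11%) of the intact level, and Sst, which encodes the peptide somatostatin of an interneuron class, was at least 460-fold lower. In proliferating cells the same list had 3 members higher and 6 lower (4 and 6 adjusted over the list alone; camera adjusted p = 0.785).

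**Figure D2:**
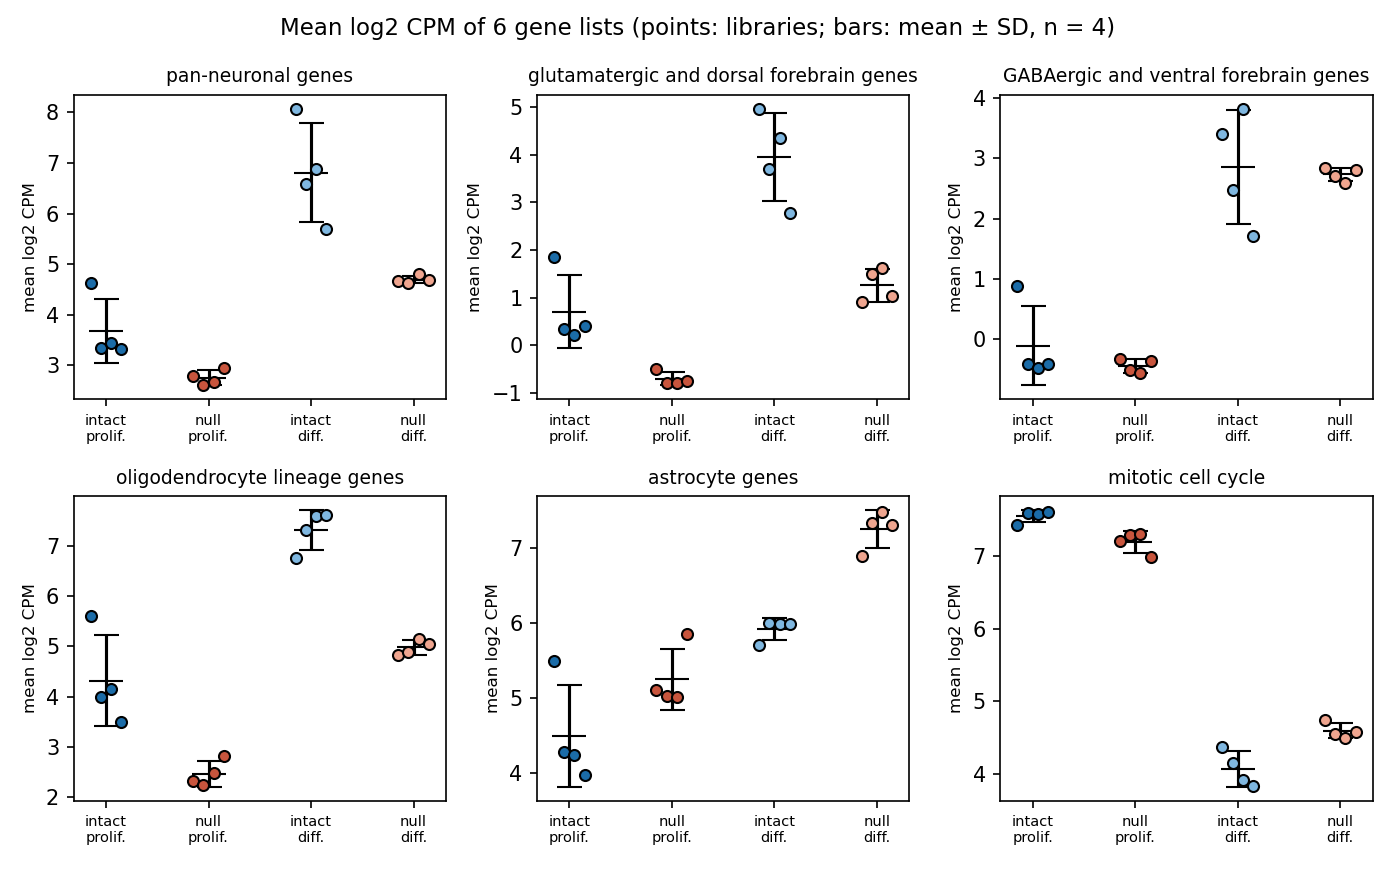
Mean log2 CPM over the members of 6 gene lists (y axis, log2 CPM) in each of the 4 groups (x axis), with 1 point per library and bars for the mean ± SD of 4 libraries. For pan-neuronal genes the null differentiating libraries lie between 4.63 and 4.80 and the intact differentiating libraries between 5.70 and 8.07.

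Oligodendrocyte lineage genes were lower and astrocyte genes higher in null differentiating cells, although single members differed from proliferating cells. Cspg4 was level with intact cells (-0.09 ± 0.20, edgeR adjusted p = 0.742) and Fgfr3 was higher (0.84 ± 0.11). All 20 called members among 24 oligodendrocyte lineage genes were lower, over all genes and adjusted over the list alone (median -2.04, camera adjusted p = 1.2e-06, adjusted p = 0.537 with an estimated correlation). Sox10 was at 62.7 ± 23.8 against 452 ± 156 CPM (-2.85 ± 0.47, edgeR adjusted p = 1.6e-04) and Ugt8a at 6.79 ± 1.57 against 271 ± 80.5 CPM (-5.31 ± 0.40). Of 25 astrocyte genes, 18 were higher and 1 lower, again in both adjustments (median 1.39, camera adjusted p = 8.3e-06, adjusted p = 0.537 with an estimated correlation). Slc1a2 reached 504 ± 87.1 against 102 ± 37.5 CPM (2.30 ± 0.23, edgeR adjusted p = 2.5e-06), Sparcl1 1900 ± 371 against 387 ± 45.3 CPM (2.30 ± 0.23) and the neurotensin receptor gene Ntsr2 rose by 3.79 ± 0.31. Intact differentiating replicate 1 had a mean log2 CPM of 5.70 over the astrocyte list, against 5.99 in the other 3 intact libraries. Without it and intact proliferating replicate 1, 21 members rose and 1 fell.

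Cell cycle and progenitor genes were higher in the null differentiating cells. Mki67, a marker of cycling cells, was at 117 ± 5.19 against 54.1 ± 13.4 CPM (1.11 ± 0.16, edgeR adjusted p = 6.8e-05). Top2a rose by 0.92 ± 0.11 (edgeR adjusted p = 1.1e-05) and Mcm3, a subunit of the replicative helicase, by 1.13 ± 0.15 (edgeR adjusted p = 2.4e-05). Of 24 mitotic genes, 19 rose and 1 fell, with 20 and 1 adjusted over the list alone (median 0.54, camera adjusted p = 1.3e-05, adjusted p = 0.537 with an estimated correlation). Of 24 DNA replication licensing genes, 15 rose and none fell, with 15 and 2 adjusted over the list alone (median 0.40, camera adjusted p = 0.0016, adjusted p = 0.560 with an estimated correlation). Egfr, which encodes the receptor of a progenitor mitogen, was at 330 ± 14.2 against 61.7 ± 12.8 CPM (2.42 ± 0.12, edgeR adjusted p = 7.1e-09). Vim was higher (1.15 ± 0.16) and Tnc lower (-2.24 ± 0.22). Of 25 neural stem cell genes, 14 rose and 4 fell in both adjustments (median 0.52, camera adjusted p = 0.048, adjusted p = 0.537 with an estimated correlation). This last call was lost without the pair of libraries apart (camera adjusted p = 0.172), under a stricter count filter (0.0579), with a replicate block (0.0629) and without any 1 of 4 libraries (0.0525 to 0.144).

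p53 targets rose with them, and cholesterol synthesis genes fell. Of 28 p53 target genes, 14 were higher and 3 lower, with 18 and 3 adjusted over the list alone (median 0.41, camera adjusted p = 0.0016, adjusted p = 0.560 with an estimated correlation). Ddit4l rose by 4.56 ± 0.17 (edgeR adjusted p = 2.4e-10) and the death receptor gene Eda2r by 2.20 ± 0.25. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases (1.85 ± 0.31), and Cdkn2a (2.33 ± 0.41) were 2 of 4 higher members among 12 CDK inhibitor and senescence genes, a list with 2 lower members and no call (camera adjusted p = 0.753, the same counts over the list alone). Of 21 cholesterol synthesis genes, 18 fell and none rose in both adjustments (median -0.52, camera adjusted p = 1.2e-06, adjusted p = 0.537 with an estimated correlation). Dhcr7 fell by 0.62 and Fdps by 0.81 on the log2 scale. Both falls did not pass the test against 1.5-fold.

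WNT and BMP target genes and Notch pathway genes were not called as lists. Among 15 WNT and BMP target genes, 6 were higher and 8 lower (the same over the list alone; camera adjusted p = 0.322). Of the 4 called members with the lowest adjusted p, Id1 (1.90 ± 0.690 against 38.4 ± 9.89 CPM, -4.35 ± 0.43, edgeR adjusted p = 2.2e-06) and Id3 (-2.87 ± 0.24) were lower, and Nkd1 (2.64 ± 0.22) and Axin2 (0.91 ± 0.12) were higher. Of 19 Notch pathway genes, 8 were higher and 2 lower in both adjustments (camera adjusted p = 0.10), with the ligand genes Dll1 (1.59 ± 0.24) and Dll4 (2.76 ± 0.36) among the higher. In proliferating cells the same 2 lists had 5 higher and 6 lower (6 and 6 over the list alone; camera adjusted p = 0.958), and 3 higher and 4 lower (3 and 4; 0.785).

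Other acetyltransferase genes rose modestly in null differentiating cells. Of 15 on the list, 7 rose and none fell in both adjustments (median 0.20, camera adjusted p = 0.017, adjusted p = 0.537 with an estimated correlation). Lowest in adjusted p were Hat1, which acetylates newly made histone H4 (0.98 ± 0.11), and Ncoa3 (0.56 ± 0.08), the latter not passing the test against 1.5-fold. In proliferating cells 3 rose and 1 fell (2 and 1 over the list alone; camera adjusted p = 0.326). Among the 10 subunits of KAT7 complexes, Jade2 rose in proliferating (2.57 ± 0.23, edgeR adjusted p = 1.3e-06) and in differentiating cells (1.39 ± 0.22, edgeR adjusted p = 1.4e-04). Kat7 itself set the mean of that list, which was -1.07 in differentiating cells beside a median of 0.20 (4 higher, 1 lower; 4 and 2 over the list alone; camera direction up, adjusted p = 0.753). In proliferating cells the mean was -0.82 beside a median of -0.02 (2 higher, 2 lower in both adjustments; 0.934). Of 13 mitochondrially encoded genes, 9 were higher and none lower in differentiating cells in both adjustments (median 0.54, camera adjusted p = 0.017, adjusted p = 0.691 with an estimated correlation), including the cytochrome oxidase gene COX1 (0.69 ± 0.16), which did not pass the test against 1.5-fold. In proliferating cells 4 were higher and 0 lower in both adjustments (camera adjusted p = 0.0900). Of 15 pericyte and fibroblast genes, 10 were lower and 2 higher (11 and 2 over the list alone; median -2.97, camera adjusted p = 0.017, adjusted p = 0.537 with an estimated correlation), among the lower Col1a1 (-3.47 ± 0.60). In proliferating cells 6 were lower and 2 higher (7 and 2; camera adjusted p = 0.326). The mitochondrial call was lost without intact differentiating replicate 3 (camera adjusted p = 0.0606) and the pericyte call under library size scaling (0.0553).

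In all, 3691 genes were higher and 3345 lower in null than in intact differentiating cells (980 and 1851 by more than 2-fold). Together they were 46.4% of all tested genes, the share beside which the numbers of called list members stand. Library size scaling alone gave 2677 higher and 4123 lower, a lower share of 60.6% rather than 47.5%. Lin7a (at least 665-fold lower), the glutamate receptor gene Grm7 (at least 503-fold), Sst, Rit2 (at least 379-fold) and Vstm2b (at least 376-fold) had no counts in null differentiating cells. Sla, Rbfox1, Lrfn5 and Lingo2 were at 0.0230% (0.00279 to 0.0832%), 0.0402% (0.00828 to 0.117%), 0.0382% (0.000967 to 0.213%) and 0.0513% (0.00130 to 0.286%) of the intact level. Higher were Hspb1 (intact cells at 0.721%, 0.148 to 2.12%, of the null level), the vasodilator peptide gene Adm (11.2 ± 3.65 against 0.243 ± 0.149 CPM, 5.52 ± 0.39, edgeR adjusted p = 1.1e-07) and Dbx2, a homeobox gene of neural progenitors (61.5 ± 4.12 against 1.39 ± 0.553 CPM, 5.43 ± 0.33, edgeR adjusted p = 2.6e-08). Fnd3c2 and Fndc3c1, Sox18, Ripply1, Klf14, Klhdc7a and Actc1 (4.66 ± 0.59) completed the 10 largest rises. By the same rule, the genotypes did not overlap for any of these genes. Of the 35 splits of the 8 differentiating libraries, 2, with the real one, called 13 lists or more.

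**Figure D3:**
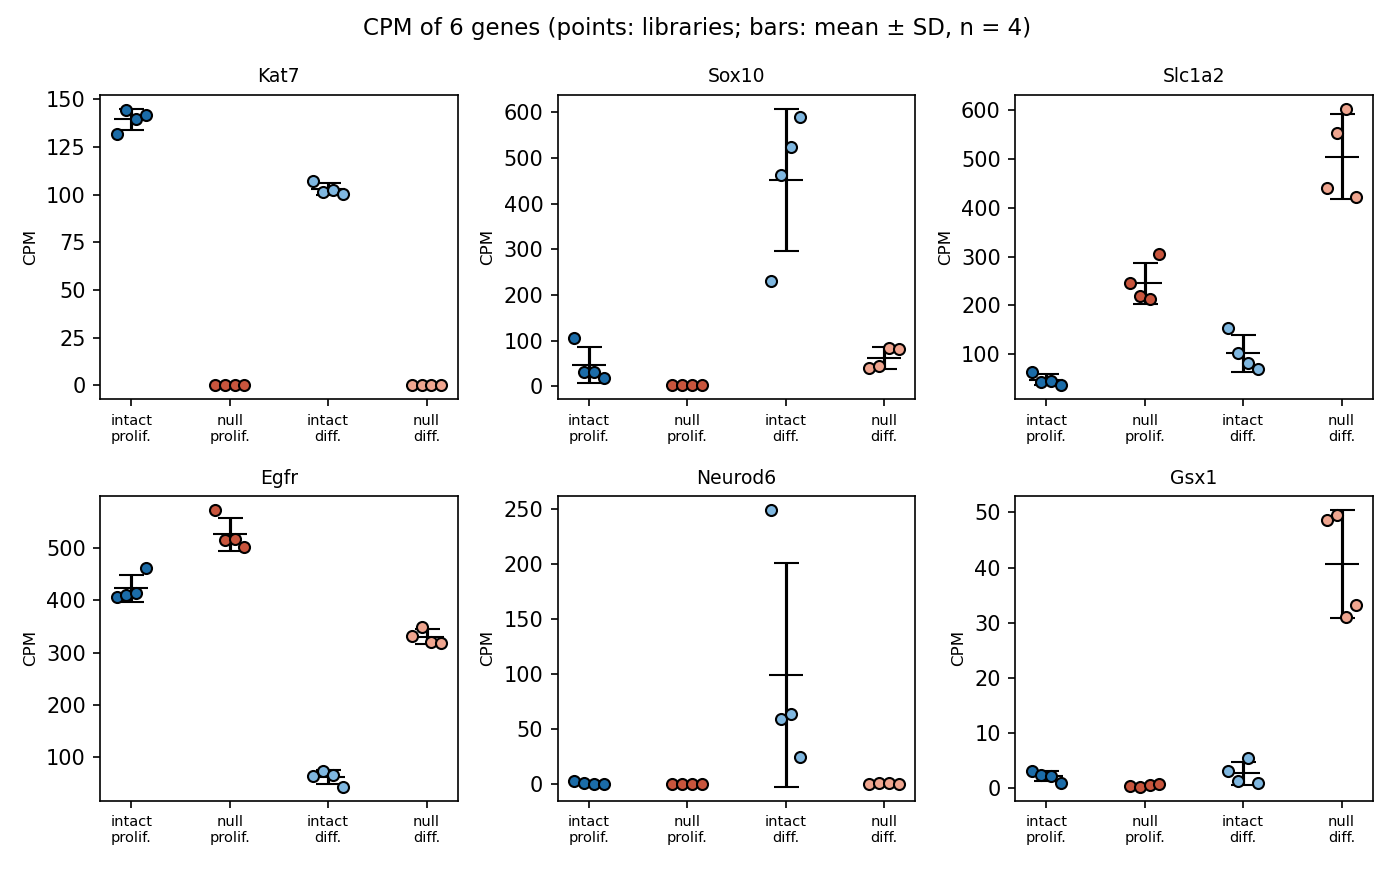
CPM of Kat7, Sox10, Slc1a2, Egfr, Neurod6 and Gsx1 (y axes) in each of the 4 groups (x axes), with 1 point per library and bars for the mean ± SD of 4 libraries. Kat7 is at 0.0899 ± 0.0718 CPM in null proliferating cells and 0.00766 ± 0.0153 CPM in null differentiating cells, and Gsx1 at 40.6 ± 9.83 CPM in null differentiating cells.

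Much of the genotype effect was shared between conditions. In the same direction, 1486 genes were higher and 1497 lower in both, where independent lists of these sizes would share 700 and 658. Opposite directions were found for 193 and 239 genes, where 635 and 726 would be shared. Cells of the same foetuses may underlie both contrasts, so the lists need not be independent even without a shared effect of genotype. Across all tested genes the 2 effects correlated with a Pearson r of 0.69 and a Spearman rho of 0.49, genes not being independent replicates.

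Intact cells lost cell cycle transcripts and gained neuronal and glial transcripts upon differentiation. All 24 mitotic genes fell (median -3.49, camera adjusted p = 1.2e-17), with Mki67 going from 598 ± 66.3 to 54.1 ± 13.4 CPM (-3.47 ± 0.18, edgeR adjusted p = 3.2e-10). Of 24 licensing genes, 22 fell and 1 rose (median -2.54, camera adjusted p = 4.3e-11). Of 30 pan-neuronal genes 29 rose (3.18, camera adjusted p = 4.3e-07), among them Elavl3 (3.59 ± 0.33). Dcx went from 14.9 ± 14.0 to 848 ± 636 CPM (5.84 ± 0.71, edgeR adjusted p = 3.5e-06), intact proliferating replicate 1 having 35.6 CPM and the other 3 an average of 7.94 CPM. Members rose in the GABAergic (16 of 21), glutamatergic (16 of 19, 2 lower), synapse (29 of 35, 2 lower), oligodendrocyte (19 of 24, 3 lower) and astrocyte lists (17 of 25, 4 lower), with camera adjusted p of 1.8e-04, 9.9e-04, 1.6e-05, 1.8e-04 and 0.025. Falls prevailed among p53 targets (24 of 28, 2 higher; 1.7e-06), CDK inhibitors (8 of 12, 2 higher; 0.011), hypoxia and glycolysis genes (12 of 20, 5 higher; 0.019), cholesterol synthesis genes (15 of 21; 0.0038) and immediate early genes (12 of 18, 1 higher; 3.0e-04). Adjusted over the list alone, 1 pan-neuronal and 1 GABAergic member also fell and 16 cholesterol genes did, and the other counts were equal. With an estimated correlation these 13 lists had adjusted p between 0.385 and 0.687. The hypoxia call was lost without intact proliferating replicate 1 (camera adjusted p = 0.0511) and the astrocyte call under a stricter count filter (0.0501).

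The largest single responses in intact cells were falls of Tnfsf18 (at least 154-fold), Cd93 (-8.90 ± 0.34, edgeR adjusted p = 1.6e-11), Anxa3, Angpt2 and the hedgehog ligand gene Dhh (-7.59 ± 0.24, edgeR adjusted p = 5.0e-12). Raet1e dropped to 0.275% (0.00693 to 1.54%) of its proliferating level. Bhlhe22 rose by 7.61 ± 0.91 and Dlx5 by 6.95 ± 0.60, with Cacng2 also higher. Proliferating cells had 0.487% (0.0123 to 2.73%), 0.572% (0.0691 to 2.08%) and 0.616% (0.127 to 1.81%) of the differentiating level of Smim18, Gdf10 and Grm2. In all, 5566 genes were higher and 5360 lower in differentiating cells (2984 and 2021 by more than 2-fold), together 72.0% of all tested genes.

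Null cells changed a similar number of genes, 69.0% of those tested, with 5248 higher and 5220 lower (2434 and 2056 by more than 2-fold). They shared 3981 rises and 4208 falls with intact cells, where independent lists would share 1925 and 1844. Across genes the responses correlated with a Pearson r of 0.76 and a Spearman rho of 0.79. All 24 mitotic genes fell again (median -2.48, camera adjusted p = 9.0e-16) and so did 22 of 24 licensing genes, with 1 higher (2.6e-09). Pan-neuronal genes rose in 20 of 30 cases, with 1 lower (median 1.43, camera adjusted p = 4.0e-04). Dcx went from 0.724 ± 0.873 to 343 ± 19.7 CPM (8.64 ± 0.86, edgeR adjusted p = 4.1e-07). Rises outnumbered falls in the GABAergic (14 to 0 of 21), glutamatergic (9 to 2 of 19; 9 to 1 over the list alone), astrocyte (20 to 1 of 25), oligodendrocyte (15 to 3 of 24) and synapse lists (21 to 4 of 35), with camera adjusted p of 1.5e-04, 0.012, 3.4e-04, 0.0033 and 0.0013. Falls outnumbered rises among p53 targets (22 to 3), CDK inhibitors (8 to 2), stress response (13 to 1), hypoxia (13 to 5), cholesterol (20 to 0) and immediate early genes (12 to 2), with camera adjusted p of 3.4e-04, 0.041, 0.0058, 0.012, 5.2e-07 and 0.013. Over the list alone the other counts were equal, and with an estimated correlation these 14 lists had adjusted p between 0.546 and 0.594. Tnfsf18, F2rl2 and Esm1 became at least 532-, 164- and 136-fold lower, Rab26 fell by 10.95 and Cd93 fell by 8.80, and Thbd was left at 0.157% (0.00397 to 0.881%). Nrxn3, Nhlh1, Cbln2 and Lgi4 rose at least 276-, 186-, 112- and 94.9-fold from 0 counts. Dlx5 and Dlx1as rose from 0.0750% (0.00190 to 0.418%) and 0.114% (0.00288 to 0.635%) of their differentiating level. The CDK inhibitor call was lost under a stricter count filter (camera adjusted p = 0.0795).

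The response to differentiation differed between genotypes, by the interaction test, for 3442 genes, 22.7% of those tested. Of these, 1935 had a higher and 1507 a lower log2 response in null cells (618 and 741 by more than 2-fold). Mitotic genes fell less in null cells, and 21 of 24 had a higher response and none a lower (22 and 0 adjusted over the list alone; median 0.86, camera adjusted p = 1.2e-12), as for Mki67 (1.47 ± 0.23, edgeR adjusted p = 5.2e-04). Licensing genes (12 higher, 0 lower of 24; 16 and 0 over the list alone; 0.49, camera adjusted p = 2.9e-05) and p53 targets (10 and 1 of 28 in both adjustments; 0.54, camera adjusted p = 0.0015) followed. Egfr fell by 2.78 ± 0.12 in intact cells and by 0.67 ± 0.12 in null cells (interaction 2.10 ± 0.17, edgeR adjusted p = 3.9e-06). Responses were lower for pan-neuronal genes (8 of 30, none higher; 10 and 1 over the list alone; median -1.09, camera adjusted p = 0.0056) and for stress response genes (7 of 20, none higher; 9 and 0; -0.55, camera adjusted p = 6.8e-04). So were those of cholesterol synthesis genes (11 of 21, none higher; 13 and 0 over the list alone; -0.47, camera adjusted p = 2.6e-06). Neural stem cell genes (7 higher, 1 lower of 25; 0.36, camera adjusted p = 0.046) and astrocyte genes (6 and 1 of 25; 0.90, camera adjusted p = 0.049) passed narrowly, with the same counts over the list alone. The astrocyte call was lost without any 1 of 7 libraries (camera adjusted p = 0.0521 to 0.182), its median dropping to 0.14 without intact proliferating replicate 1, and the stem cell call without any 1 of 4 (0.0573 to 0.115). With an estimated correlation these 8 lists had adjusted p between 0.712 and 0.855. The stem cell and astrocyte calls were lost with the replicate block (camera adjusted p = 0.0564 and 0.0594), under the stricter filter (0.0502 each) and without the pair of libraries apart (0.170 and 0.355; astrocyte median 0.05). The pan-neuronal call was lost without intact differentiating replicate 1 (median -0.64, camera adjusted p = 0.0675) and with fry (adjusted p = 0.266), as was the astrocyte call (0.153).

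Single genes with the largest differences in response were Gsx1 (6.15 ± 0.74, edgeR adjusted p = 8.8e-05), Sox18 (6.35 ± 1.29), Bmp3 (6.08 ± 0.88), Adamtsl3 (6.0 ± 0.85) and Tafa4 (5.88 ± 0.56), with a higher response in null cells. A lower response was found for Mobp, a myelin gene (-7.17 ± 1.06, edgeR adjusted p = 3.2e-04), Gria1 (-10.16 ± 1.99), Hs3st2 (-8.06 ± 1.73), Eef1a2 (-7.91 ± 1.30) and Inpp5j (-7.89 ± 1.48). Nrxn3 and Hs3st4 also passed (edgeR adjusted p = 0.0015 and 0.037) but had a group without counts, so that the size of their difference depends on the prior count. Gria1 lost its call without null proliferating replicate 4 (-4.66, edgeR adjusted p = 0.283) and with limma voom quality weights (-4.72, voom adjusted p = 0.154).

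Genes that are switched on upon differentiation reached a lower level in null cells. Over 818 genes that rose on the mean of both genotypes and had a mean under 0.5 CPM in proliferating cells, the mean log2 CPM was -0.69 ± 0.06 in null and 0.57 ± 0.40 in intact differentiating libraries, a difference of -1.26. The exact two-sided permutation test gave p = 0.0286, the smallest that 70 splits of 4 against 4 can give. For 1903 rising genes at 0.5 CPM or more the difference was -0.65 (exact two-sided p = 0.0286). It was -1.27 for those with a mean log2 fold change over 2. Differences of -0.51 and -0.52 were already present between the proliferating libraries (exact two-sided p = 0.0286 for each), and intact proliferating replicate 1 carried much of them. Its means were -1.24 and 3.30, those of the other 3 intact libraries averaged -2.38 and 2.41, and those of the null libraries -2.60 and 2.12. For 2003 falling genes the difference in differentiating cells was 0.14 (exact two-sided p = 0.114). The median interaction was -0.37 for the first set (-0.40 without 99 genes with a group at 0 counts), -0.01 for the second and 0.16 for the falling genes. Interaction calls numbered 40 lower and 29 higher, 217 and 243, and 250 and 452 in the 3 sets. Without the pair of libraries apart the difference for the second set was -0.41.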

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

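Chosen only after the result was seen were the tests of a label swap, of sequencing depth and of 1 shared proportion for all genes in intact proliferating replicate 1, and the tests of a lower share of neurons and of 1 fold for all neuronal genes. The splits for the number of lists in the stage contrasts and the interaction, and the values without the pair of libraries apart, were also chosen then.

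Intact proliferating replicate 1 lay far from the other 3 libraries of its group, by Dixon's ratio, for 15 of the 29 values tested in that group. Over all 4 groups, 25 of 116 sets of values (21.6%) had such a library, where chance alone gives about 1 in 20 for normally distributed values. The values are not independent, since neuronal and other genes count both singly and in lists. A shift of 1 library is thus counted many times. The depth of intact proliferating replicate 1, 19.6 M counts, lay inside the range of the other 3, and the lowest score of an intact differentiating library on component 1 was 102, which leaves no partner for a swap with that group. RNA of intact differentiating cells in this library may account for part of the pattern: 65.0% of the genes that rose at least 4-fold upon differentiation gave a proportion within 2-fold of their median of 12.2%, between the bounds of 50 and 80% set beforehand, which leaves a mixture undecided. A single proportion for every gene was argued against by the p53 targets, the most extreme of 7 lists looked at. They gave 62.9% (middle range 51.7 to 66.6%) beside 12.4% (7.68 to 15.2%) for mitotic genes. Other genes also differed. Genes falling at least 4-fold gave 25.1% (14.2 to 41.8%), a range that overlaps that of the rising genes (7.36 to 19.8%). Pan-neuronal genes gave 7.76% (4.77 to 12.1%) and glutamatergic genes 2.67%. Oligodendrocyte lineage genes gave 14.4% (12.8 to 18.3%) and astrocyte genes 20.4% (15.7 to 22.8%), above the pan-neuronal range. GABAergic genes, at 5.7% (5.36 to 15.4%), overlapped pan-neuronal and oligodendrocyte genes. Some differentiation inside that culture, or a mixture with separate changes of p53 targets and other genes, was not tested and stays open.

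Neuronal, glutamatergic and synapse genes were lower in null differentiating cells, and this pattern was weighed against scaling, gene length and a lower share of neurons. With library size scaling alone 21 of 30 pan-neuronal genes were still lower. That scaling moved the median log2 fold change of all genes from 0.037 to -0.051, which favours lower calls. It therefore could not test scaling as a cause, although the move was small beside the pan-neuronal median of -1.48. Beside genes of the same length and expression the median of the 84 genes of the 3 lists was still -1.26 lower (quartiles -3.61 and -0.31), so length was not the whole cause. A smaller share of neurons remains possible, since 50% of the pan-neuronal genes lay within 1 log2 unit of their median, on the bound of 50% below which the test would have excluded it. One fold for all neuronal genes was argued against by 17 of 30 genes lying over 2 SE from the list's median, Syt4 the lowest at -9.49. The SE can be too small for genes with few counts in null cells, so 17 may be too many. A change in the kind or maturity of neurons, alone or with their share, may underlie this unevenness and was not tested.

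Genes near Kat7 on chromosome 11 were examined for sequence of another mouse strain around the targeted allele, which could alter read counts there. Within 10 Mb of Kat7, 158 of 258 genes were called in a genotype contrast (61.2%) against 63.6% of all others, a ratio of 0.963 (Fisher's exact two-sided p = 0.434). No excess of called genes was found there, but with most genes called the bar of 1.5 was close to the highest ratio possible, so effects of strain sequence on single genes stay open.

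The real split of the libraries called more genes than any other split in each contrast. Proliferating genotypes had 5864 against at most 114 in any other split, and differentiating genotypes 7036 against 0. The responses of intact and null cells had 10926 against 2213 and 10468 against 2, and the interaction 3442 against 2260. Genes called in the same direction in both conditions were 2983 against 0, a 0 that follows where other splits call almost no genes. Chance alone would place the real split first in 1 of 35 splits, or 1 of 60 drawn, so it is made unlikely but not excluded. Other splits mix libraries of both groups, which adds a real difference to the spread within groups. Their low counts therefore do not measure how many calls chance gives. For the number of lists called by camera, other splits reached the real value in all contrasts but 1. At least as many lists were called in 23 of 35 splits for proliferating genotypes (6 lists, up to 11) and 2 of 35 for differentiating genotypes (13, the other with 13). The same held for 4 of 35 in the intact response (13, up to 14) and 31 of 60 in the interaction (8, up to 12). Only the real split reached 14 lists in the null response (1 of 35, highest other 13). Other splits that keep most libraries of a group together still carry part of the real difference. Those with 2 libraries of each group on each side carry no net difference between the groups. For proliferating genotypes, the highest count of 11 lists came from splits of this second kind. Camera at its preset correlation can thus call as many lists there without a net genotype difference. The numbers of lists therefore neither exclude nor show chance in any contrast.

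Other values of intact proliferating replicate 1 far from its group were the CPM of Ugt8a (48.0, other libraries averaging 15.8; ratio of gap to range 0.841), Sox10 (107 against 27.0; 0.851), Dcx (35.6 against 7.94; 0.868), Adm (11.2 against 22.6; 0.848), Neurod6 (2.71 against 0.235; 0.855), Dlx2 (4.26 against 0.748; 0.938), Id1 (47.9 against 13.5; 0.954) and Tubb3 (37.8 against 11; 0.934). In the same library the mean log2 CPM stood apart for pan-neuronal genes (4.63 against 3.37; 0.902), GABAergic genes (0.89 against -0.43; 0.955), glutamatergic genes (1.84 against 0.32; 0.892), mitotic genes (7.43 against 7.60; 0.830), rising genes under 0.5 CPM (-1.24 against -2.38; 0.938), rising genes at or over it (3.30 against 2.41; 0.866) and falling genes (3.88 against 4.20; 0.978). Null proliferating replicate 4 stood apart for Sparcl1 (1258 against 725 CPM; 0.991), Adm (86.6 against 55.0 CPM; 0.846), Neurod6 (0.0567 against 0 CPM; ratio 1) and astrocyte genes (log2 5.85 against 5.05; 0.901), and null proliferating replicate 1 for glutamatergic genes (-0.50 against -0.77; 0.867). Further such values were Egfr (461 against 410 CPM; 0.883) and Mki67 (696 against 565 CPM; 0.837) in intact proliferating replicate 4, astrocyte genes in intact differentiating replicate 1 (5.70 against 5.99; 0.993), Id1 in null differentiating replicate 1 (2.93 against 1.56 CPM; 0.841) and the single Kat7 count in null differentiating replicate 2 (0.0306 against 0 CPM; ratio 1).

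The genotype effect differed between culture conditions, by the interaction test of edgeR at an adjusted p under 0.05, for 46 of 97 genes named in a genotype contrast. Of all tested genes the interaction called 22.7%. The named genes were chosen for large or clear effects in a genotype contrast, which can favour such a difference. The count is therefore no result about them as a set. Above 0, the effect being higher in differentiating cells, the interaction log2 values were 7.64 for Nrxn3 (fitted with a group at 0 counts), 6.35 for Sox18, 6.15 for Gsx1, 6.0 for Adamtsl3, 4.97 for Actc1, 3.86 for Vgll2, 3.85 for Adm, 3.78 for Klhdc7a, 3.41 for Nkd1, 2.56 for Dbx2, 2.46 for Lhfpl3, 2.42 for Eda2r, 2.26 for Cdkn2a, 2.12 for Ddit4l, 2.11 for Ntsr2, 2.10 for Egfr, 2.08 for Cspg4, 1.92 for Cdkn1a, 1.72 for Fgfr3, 1.62 for Sox5 and 1.61 for Dll1. Values from 0 to 1.5 were 1.47 for Mki67, 1.37 for Vim, 1.28 for Cdc45, 1.15 for Aurkb, 1.13 for Top2a, 0.99 for Mcm3, 0.89 for Hat1 and 0.72 for Ccnb2. Negative values were -7.17 for Mobp, -6.14 for Kcne4, -5.95 for Fam43b, -5.55 for Eomes, -4.48 for Col1a1, -4.29 for Id1, -4.23 for Gria4, -4.03 for Pitx3, -4.01 for Gng3, -3.62 for Nefl, -2.85 for Fgl2, -2.34 for Crispld2, -2.20 for Id3, -1.95 for Tnc, -1.17 for Jade2, -0.67 for Fdps and -0.51 for Dhcr7.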

How the results depend on the processing

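The fit without the pair of libraries that stood apart was chosen only after the result was seen. No named gene reversed direction under an alternative in which it was tested. The test against 1.5-fold keeps the fold changes of the main fit and cannot reverse one. No called list reversed direction where lists were tested again. That was done with the other scalings and filters, the replicate block, left-out libraries, the pair left out, an estimated correlation and fry. Which direction held more called genes was not stable: differentiating genotypes had more lower than higher with DESeq2 size factors (3116 higher, 3715 lower), library size (2677 and 4123), no filter (3553 and 3684), only the libraries compared (3046 and 3588) and DESeq2's test (3268 and 4133), as did the interaction with the last (1979 and 2100) and both with the test against 1.5-fold. Proliferating genotypes had more higher than lower without the pair (3682 and 3671), with isolate as a random block, without intact proliferating replicate 1 (3186 and 3068) and without null proliferating replicate 1 (2607 and 2605). The null response had more lower without null proliferating replicate 2 (4943 and 5103) or 3 (4913 and 5073). Counts stayed within 1.5 times of those reported under the other scalings, filters and blocks, DESeq2's Wald test, the fit of only the libraries compared and each left-out library; for the latter, genes higher in null proliferating cells ranged from 2405 to 3186 and those with a lower response from 1210 to 1857. With replicate number as a block the calls were 2753 higher and 2887 lower for proliferating genotypes and 3560 and 3183 for differentiating genotypes. The interaction then gave 1796 and 1355. The isolate blocks assumed that libraries of a genotype with the same number came from 1 foetus, which is not known. With isolate as a fixed block the interaction gave 1648 and 1277. As a random block (correlation 0.01) the genotype contrasts gave 2748 and 2666, and 3845 and 3331. If the numbers do not match foetuses, these fits do not account for shared foetuses.

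The test against 1.5-fold called fewer genes, by its construction: 627 higher and 1018 lower (proliferating genotypes), 958 and 1683 (differentiating genotypes), 3142 and 2588 (intact response), 2653 and 2497 (null response), 359 and 407 (interaction), 286 and 654 (shared between conditions). Quality weights in voom called more, 4498 and 4712 (proliferating genotypes), 3948 and 3139 (interaction), 2453 and 2287 (shared); the cause was not tested. For the activated genes, choice on intact replicates 1 and 2 alone gave -1.87 and -1.19 (exact p = 0.0667, the smallest possible with fewer libraries; choice on intact cells alone favours a higher intact level), and leaving out the pair gave -0.41 for the second set, where leaving out only intact differentiating replicate 1 gave -0.56.

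Of 193 named gene results, 11 lost their call against 1.5-fold, 2 with the random block (Bmp4, adjusted p = 0.0586, and Sp9, 0.0722, in proliferating cells) and 1 with voom (Gria1). The interaction of Hs3st4 lost its call without any 1 of 8 libraries. Of 54 list calls, all were lost with an estimated correlation, 2 with fry, 2 with library size scaling, 3 with the replicate block, 5 with the strict filter and 4 without the pair. Leaving out 1 library at a time ended a call in 19 of 496 list results, 15 of them for neural stem cell or astrocyte genes. Sex as a covariate was not run, since all libraries read as 1 sex. Depth limits the bounds on genes without counts, and in the simulated data the interaction recovered 53% of planted 2-fold changes.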

Other observations

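Interferon, hypoxia and immediate early genes were not called as lists in either genotype contrast, while single members changed. Of 15 interferon response genes, 5 were lower and 1 higher in null proliferating cells and 2 and 2 in differentiating cells (5 and 1, and 1 and 1, adjusted over the list alone), without a call (camera adjusted p = 0.0900 and 0.891). Ifit2 was higher in both conditions (1.46 ± 0.14 and 1.77 ± 0.14, edgeR adjusted p = 2.4e-06 and 3.0e-07). Of 20 hypoxia and glycolysis genes, 6 were higher and 3 lower, and 6 and 1 (6 and 4, and 6 and 1, over the list alone; camera adjusted p = 0.106 and 0.322). Ndrg1 fell by 6.79 ± 0.86 in null differentiating cells (edgeR adjusted p = 1.9e-05), while the glycolytic enzyme gene Aldoa rose by 0.72 ± 0.08 in each condition. Of 18 immediate early genes, 2 were higher and 3 lower, and 4 and 4, in both adjustments (camera adjusted p = 0.220 and 0.753), with Arc, a gene of neuronal activity, lower in both (-2.26 ± 0.25 and -2.20 ± 0.29). The 20 stress response genes, higher in proliferating null cells, had 4 higher and 7 lower in differentiating null cells in both adjustments (camera adjusted p = 0.753), with Xbp1 lower (-1.13 ± 0.12) and Slc7a11 still at 211 ± 33.9 against 24.7 ± 7.43 CPM. Cholesterol synthesis genes had 3 higher and 2 lower of 21 in proliferating cells (camera adjusted p = 0.785), and CDK inhibitor genes 1 higher and 2 lower of 12 (0.770), in both adjustments.

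Ependymal, neural crest, endothelial, microglia and non-neural genes were not called as lists in a genotype contrast, unlike pericyte and fibroblast genes in differentiating cells. Of 11 tested ependymal and choroid plexus genes, 3 were higher and 1 lower in null proliferating cells and 2 and 2 in differentiating cells in both adjustments (camera adjusted p = 0.469 and 0.753). Foxj1, the regulator of motile cilia, rose by 0.87 ± 0.14 and 1.39 ± 0.14, and Dnah9, an axonemal dynein, was at 7.47% (1.46 to 23.9%) of the intact level in proliferating cells and fell by 6.78 ± 0.49 in differentiating cells. The ependymal median and mean differed in sign in differentiating cells (0.60 and -0.22, camera direction up). Of 8 neural crest and Schwann cell genes, 2 of which the oligodendrocyte list also holds, 3 were higher and 2 lower, and 3 and 4 (3 and 3, and 3 and 4, over the list alone; camera adjusted p = 0.996 and 0.753). Of 9 endothelial genes, 1 was higher and 1 lower in each condition in both adjustments (0.859 and 0.753), with Sox18 the higher member in differentiating cells. Of 2 microglia and leukocyte genes, 1 was higher in proliferating and none in differentiating cells (0.682 and 0.859). Of 3 non-neural lineage regulators, 0 were called in proliferating cells and 1 higher and 1 lower in differentiating cells (2 and 1 over the list alone; 0.934 and 0.891). The lower member was Eomes, and the list's median of 1.08 and mean of -0.80 in differentiating cells differed in sign.

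A hypothesis, tested only after the result was seen, is that genes off in proliferating cells need KAT7 more upon differentiation than genes already on. Of the interaction calls, 58.0% were lower among rising genes under 0.5 CPM and 47.2% among the other rising genes, a difference of 10.8 percentage points (Fisher's exact two-sided p = 0.121). These counts leave the hypothesis open. Fisher's test takes genes of the same libraries as independent, so its p does not measure the variation between libraries. In proliferating cells the first set already differed by -0.51 between genotypes, largely through intact proliferating replicate 1 (-1.24, other 3 intact libraries -2.38, null libraries -2.60).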
